A study of Solanum tuberosum with 9 samples.

How the data were processed

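Messenger RNA from potato tubers (Solanum tuberosum, cultivar Keshan) was profiled in 9 libraries, 3 each from control tubers at day 0 of storage, control tubers at day 40 and tubers fumigated with rosemary essential oil (REO, a volatile plant oil) at day 40. Per the labels' protocols, RNA was taken with TRIzol, treated with DNase I, selected on oligo(dT) beads, fragmented and primed with random hexamers. No strand-marking step is described, so reads of a gene and of an antisense partner may not have been told apart. The series text calls the libraries biological replicates and does not give the number of tubers behind each, and the p-values measure only the spread between these libraries.

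The authors deposited a table of whole-number counts and a second table of normalised values over the same 34239 gene models and 9 libraries. HISAT2 2.1.0 and DESeq2 are listed per the submitters' processing notes. The counting tool, the genome build and the annotation are not given in the sources used here. Of the gene models, 32819 carry an identifier with a chromosome number, 98 an identifier for unplaced sequence and 1322 an identifier added by the submitters. No column lacked a sample and no row lacked an identifier. The deposited counts were used without change. The value 1 occurred 1998 times in the count table and the value 2 occurred 4901 times, so both mates of a pair may have been counted and the counts are then not independent fragments. The second deposited table was read as FPKM from its values: in 92.6% of 6912 well-covered models, the ratio of count to value was a gene constant times a library constant within 2% in every library. It served for alternatives on a log2(FPKM + pseudocount) scale, which understates the change of low genes, and for a length scale of each model from the ratio of count to value.

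The files do not pair the identifiers with gene names. None of the identifiers (0) matched the reference gene table provided, which belongs to assembly SolTub_3.0. The 44 gene lists of hormone, carbohydrate, defence, cell cycle and tissue-marker genes fixed before the data were examined therefore had 0 testable members and are not reported. Gene models are named by identifier, with at most 2 that rose and 2 that fell per comparison. The rule for these was also fixed before the data were examined: adjusted p under 0.05, all 3 libraries of one group above all 3 of the other, a mean of at least 5 CPM (counts scaled to library size) in the higher group, and then the largest fold change. The rule's condition of a descriptive name could not be applied. The chromosome given for a model is the number in its identifier, and no coordinates are used here. How reads of near-identical or overlapping models were divided is not given in the sources used here, so their counts are uncertain.

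Library totals ranged from 29330673 to 36901701 counts, and the floor of 3 counts corresponded to 0.0813 to 0.102 CPM. Floors and intervals cover counting error only. Models with too few counts were removed with filterByExpr in edgeR 4.0.16 (R 4.3.3), which left 22638. One quasi-likelihood model with 1 coefficient per group was fitted to all 9 libraries with TMM scaling, and the 3 group contrasts were tested two-sided with Benjamini-Hochberg adjustment at 0.05. Standard errors of log2 fold changes were derived from the F statistic. CPM values are TMM-scaled. The common biological coefficient of variation, 1 value for all genes, was 0.362. The replicates of each group differed far beyond counting noise, with a chi-square per degree of freedom of at least 36.4 in every pair, so none was counted as a repeated library.

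The model was tested on simulated data, with 200 genes changed by known folds. These were drawn from genes with a mean of at least 1 CPM, so recovery of lower genes was not measured. For REO against control at day 40, 16% of the 2-fold, 80% of the 4-fold and 90% of the 8-fold changes were recovered among 22346 simulated genes, and 3 of 144 calls were false. For control day 40 against day 0 the 4-fold recovery was 64% among 22306 genes with 1 false call of 129. For REO day 40 against control day 0 it was 68% among 22336 genes with 8 false calls of 142. DESeq2 1.42.0 on the same simulated data made 70 false calls of 239, 57 of 214 and 71 of 232. The simulated counts were drawn gene by gene from dispersions that edgeR estimated, so they do not rank the methods on the real data.

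Alternatives were DESeq2, limma-voom (limma 3.58.1), 3 other scalings, 2 other low-count filters, a fit of only the 6 libraries compared, a replicate block, robust shrinkage, other thresholds, the FPKM values and leaving out each library. Added after the data were seen were leaving out 2 libraries together, library quality weights and leaving out 5 abundant models. Because the contrasts share libraries, 50 data sets with no group difference were simulated with the real library sizes and dispersions. Each gene was drawn independently.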

Results

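Tuber transcripts were measured by RNA sequencing in 3 groups of 3 libraries: control tubers at day 0, control tubers at day 40 of storage and tubers fumigated with rosemary essential oil (REO) at day 40. The series title places the work in the suppression of sprouting during storage. Total counts of replicates 1, 2 and 3 were 32413648, 34589624 and 31311367 at day 0, 36901701, 35952180 and 31234314 in control tubers at day 40, and 29330673, 35577854 and 32351224 with REO. Between 23747 and 26805 gene models had at least 1 count in a library. The files identify gene models without naming them, so gene models are given by identifier and chromosome number.

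The libraries differed within groups as well as between them. Pearson correlations of log2 CPM across genes, which are not independent replicates, were 0.956 to 0.964 within the day 0 group and 0.961 to 0.974 within the REO group. Within the control group at day 40 they were 0.898 to 0.965, and replicate 2 gave the low values. That library had 26805 detected gene models, the highest number of the 9, and its highest correlation with any library was 0.945, with REO replicate 3. The first principal component held 35.4% of the variance and placed control day 40 replicate 2, at 76.8, beside day 0 replicates 2 and 3, at 69.5 and 77.8. The second component held 23.6% and set it apart from them, at -94.8 against 25.3 and 64.4.

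**Figure D1:**
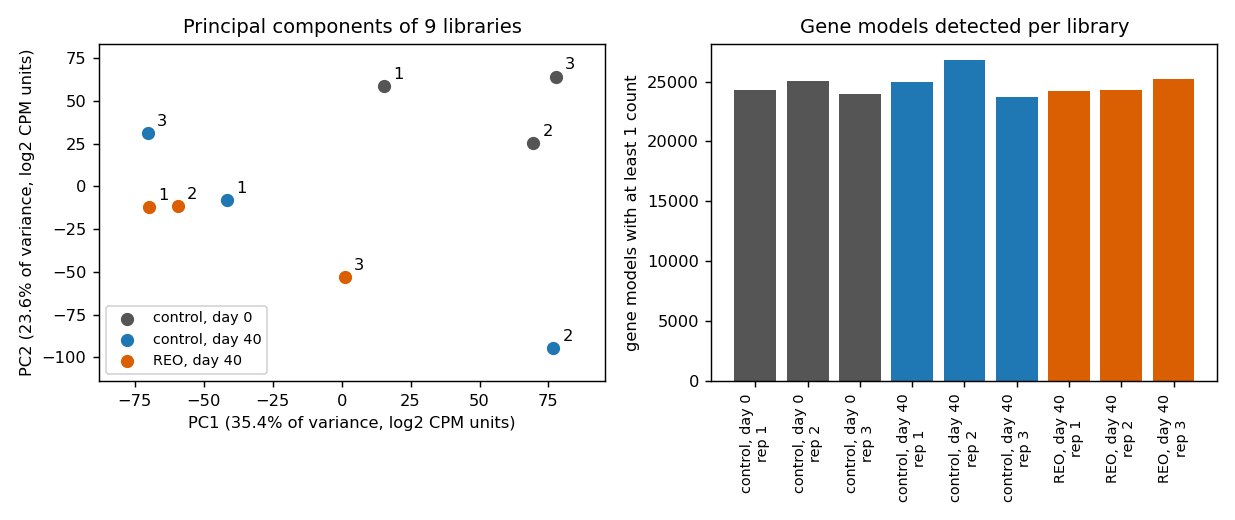
Left, the first 2 principal components of log2 CPM for the 9 libraries, coloured by group and numbered by replicate; right, the number of gene models with at least 1 count in each library. Control day 40 replicate 2 lies apart from replicates 1 and 3 of its group and has 26805 detected gene models.

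The main comparison set REO against control tubers at the same storage time, day 40. Of 22638 gene models tested, 96 were higher with REO and 8 were lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). DESeq2 called 388 higher and 128 lower, and the median log2 fold change of all tested models was -0.05. The 96 risen models had a median level of 5.05 CPM in control tubers at day 40 and 28.3 CPM with REO, against 6.08 CPM at day 0. Their summed level was 2178 CPM at day 0, 1798 CPM in control tubers at day 40 and 6383 CPM with REO. The median log2 fold change was 2.25 among the risen models, with quartiles of 1.51 and 3.15, and 27 of them rose at least 8-fold. The 8 fallen models had a median log2 fold change of -1.35, and none (0) fell 8-fold.

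The model with the largest rise was Soltu.DM.10G024690 on chromosome 10. It was under 1 CPM in every control library, at 0.226 ± 0.0745 CPM (SD, n = 3) at day 0 and 0.604 ± 0.526 CPM at day 40, and reached 320.1 ± 103 CPM with REO. In control tubers at day 40, replicates 1 and 2 had 0.846 and 0.966 CPM and replicate 3 had 0. Its log2 fold change against control day 40 was 9.00 ± 0.80 (SE), with an edgeR adjusted p of 0.00239. Soltu.DM.09G024050 on chromosome 9 rose from 0.159 ± 0.0953 to 16.7 ± 5.25 CPM, a log2 fold change of 6.65 ± 0.48 (edgeR adjusted p = 0.00103). Both rises passed the test under each of 12 alternatives, with adjusted p (edgeR or DESeq2) of 9.12e-15 to 0.0181 and of 2.81e-36 to 0.00905. Among the fallen models, Soltu.DM.05G022980 on chromosome 5 was at 38.6 ± 5.48 CPM in control tubers at day 40 and 7.97 ± 3.21 CPM with REO, a log2 fold change of -2.28 ± 0.32 (edgeR adjusted p = 0.0256). Soltu.DM.09G023770 on chromosome 9 was at 180 ± 57.3 CPM and 59.5 ± 1.32 CPM, a log2 fold change of -1.60 ± 0.23 (edgeR adjusted p = 0.0255). The calls of these 2 fallen models were lost in 6 and 7 of the 12 alternatives, with adjusted p (edgeR or DESeq2) of 1.87e-09 to 0.166 and of 5.75e-09 to 0.161. Neither changed sign, which the naming rule made hardly possible where a library was left out.

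Models risen with REO were found at all levels of expression above 1 CPM, but least often at 1 to 10 CPM. Of the risen models, 12 had a higher group mean of 1 to 10 CPM, 66 of 10 to 100 CPM and 18 of at least 100 CPM. The models tested at these levels numbered 8398, 9391 and 2007. Control tubers at day 40 held 13 of the risen models under 1 CPM. In 92 of the 96, every REO library lay above all 6 control libraries, those of day 0 included. Of the 8 fallen models, 7 lay below all 6 in every REO library. All 104 called models already separated REO from control at day 40, so only the place of the day 0 libraries was left open by the selection. Across all tested models, 725 lay above and 528 below all 6 control libraries, where chance alone gives 269.5 each (1.19%). Submitter-added models made up 2 of the risen models.

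The number of models called depended on single libraries. It was 46 without day 0 replicate 1, 37 without control day 40 replicate 3, 175 without control day 40 replicate 2, and 52, 23 and 41 without REO replicates 1, 2 and 3. All 104 models had the same sign under each of these and under DESeq2. In all 104 the REO libraries lay outside the range of the control libraries of day 40, so leaving out a library could hardly turn a sign.

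**Figure D2:**
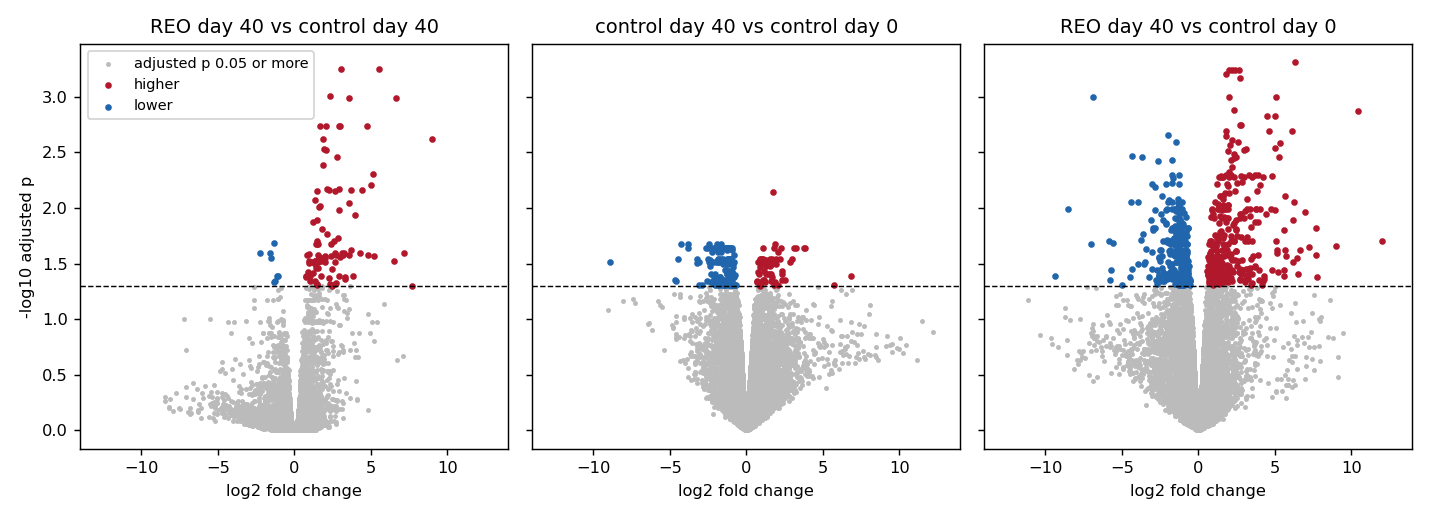
Log2 fold change (x axis) against -log10 of the edgeR adjusted p (y axis) for 22638 gene models in each of the 3 comparisons; red and blue points passed an adjusted p of 0.05 (dashed line) and were higher or lower. REO at day 40 gave 96 higher and 8 lower models against control at day 40.

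Storage without REO was compared as control day 40 against control day 0. Here more models fell than rose, 129 against 62 of the 22638 tested (edgeR quasi-likelihood test, adjusted p under 0.05). Other scalings gave 67 higher and 131 lower (RLE), 70 and 118 (upper quartile), and 63 and 65 by library size alone, which moved the median log2 fold change of all models from 0.04 to 0.16. DESeq2 gave 730 higher and 881 lower, and limma on log2(FPKM + 1) gave 144 and 150. The balance was reversed by limma on log2(FPKM + 0.1), with 147 higher and 135 lower, without control day 40 replicate 1, with 6 and 2, and without control day 40 replicate 3, with 14 and 10. The fallen models included abundant ones, 29 of them at 100 CPM or more in the higher group. Their summed level was 42780 CPM at day 0, 10670 CPM in control tubers at day 40 and 13950 CPM with REO. The 62 risen models summed to 827.3 CPM at day 0, 1898 CPM in control tubers at day 40 and 1698 CPM with REO. In 123 of the 129 fallen models every day 0 library lay above all 6 libraries of day 40, and in 60 of the 62 risen models below them. All 191 called models already separated day 0 from control day 40, as did 19.9% of all tested models. Only the place of the REO libraries was left open by the selection, and its share over all models was not computed.

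Soltu.DM.02G022040 on chromosome 2 fell from 13.9 ± 3.04 CPM (SD, n = 3) at day 0 to 0.725 ± 0.312 CPM at day 40, a log2 fold change of -4.26 ± 0.44 (edgeR adjusted p = 0.0209). Soltu.DM.08G028500 on chromosome 8 fell from 192.5 ± 53.5 to 13.6 ± 5.44 CPM, a log2 fold change of -3.83 ± 0.39 (edgeR adjusted p = 0.0209). With REO it stood at 15.2 ± 4.21 CPM at day 40. Soltu.DM.09G027170 on chromosome 9 rose from 0.927 ± 0.268 to 8.75 ± 4.26 CPM, and Soltu.DM.06G025720 on chromosome 6 rose from 1.55 ± 0.215 to 13.2 ± 6.02 CPM. Their log2 fold changes were 3.22 ± 0.42 and 3.10 ± 0.38 (edgeR adjusted p = 0.0229 for both). At day 40 with REO these 2 models stood at 12.4 ± 2.83 and 15.3 ± 4.48 CPM. Each of the 4 calls was lost in 3 to 5 of 12 alternatives, with adjusted p (edgeR or DESeq2) from 3.17e-22 to 0.0816 over the 4.

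The storage count depended on every library. Leaving out day 0 replicates 1, 2 and 3 in turn gave 3, 44 and 0 models, leaving out control day 40 replicates 1, 2 and 3 gave 8, 985 and 24, and leaving out REO replicates 1, 2 and 3 gave 54, 0 and 54. A fit of only the 6 libraries compared also called 0. These 3 edgeR fits had 3325, 3585 and 2892 models at an unadjusted p under 0.05, where the full fit had 4162, and DESeq2 on all libraries called 1611.

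Storage with REO was compared as REO day 40 against control day 0, which equals the sum of the other contrasts. This gave the most calls of the 3 in the edgeR fit, with 314 models higher and 276 lower. At an unadjusted edgeR p under 0.05 it had 4186 models, and storage without REO had nearly as many, 4162. Without control day 40 replicate 2 the calls were 1430 with REO and 985 without it, and DESeq2 called 1970 and 1611. The balance was turned by DESeq2, with 900 higher and 1070 lower, and without control day 40 replicate 2, with 701 and 729. It was also turned by 2 fits chosen after the data were seen. Library quality weights gave 1989 and 2137, and leaving out that library with REO replicate 3 gave 475 and 535. The other alternatives kept more models higher, and among them a fit of only the 6 libraries compared called 1208 in all. The risen models had a median of 4.04 CPM at day 0, 7.18 CPM in control tubers at day 40 and 15.5 CPM with REO. The fallen models had medians of 27.4, 13.9 and 11.7 CPM, and their summed level was 57990 CPM at day 0, 18510 CPM in control tubers at day 40 and 16130 CPM with REO. Of the risen models 9 had 0 counts in all day 0 libraries, and of the fallen models 2 had 0 counts in all REO libraries.

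Soltu.DM.08G011840 on chromosome 8 had 0 counts in all 3 day 0 libraries and 15.1 ± 6.14 CPM (SD, n = 3) with REO, at least 157-fold higher than a floor of 3 counts per library (edgeR adjusted p = 0.0198). In control tubers at day 40 it stood at 0.471 ± 0.512 CPM. Its log2 difference between REO and control at day 40 was 4.96 and did not pass (edgeR adjusted p = 0.134). Soltu.DM.10G024690 rose by a log2 fold change of 10.46 ± 0.88 (edgeR adjusted p = 0.00133). Soltu.DM.02G022040, which fell in storage without REO, reached 0.109 ± 0.0727 CPM with REO, a log2 fold change of -6.91 ± 0.53 against day 0 (edgeR adjusted p = 0.000995). Its difference between REO and control at day 40 was -2.66 on the log2 scale and did not pass (edgeR adjusted p = 0.0794). Soltu.DM.05G012430 on chromosome 5 fell from 6.12 ± 1.87 CPM at day 0 to 0.114 ± 0.0626 CPM with REO, a log2 fold change of -5.71 ± 1.13 (edgeR adjusted p = 0.0358). It was also low in control tubers at day 40, at 0.351 ± 0.454 CPM. Its log2 difference between REO and control at day 40 was -1.61 and did not pass (edgeR adjusted p = 0.871). Its storage change without REO, -4.09, did not pass either (edgeR adjusted p = 0.0963). The calls of Soltu.DM.08G011840 and Soltu.DM.05G012430 were each lost in 7 of 12 alternatives, with adjusted p (edgeR or DESeq2) of 1.27e-06 to 0.0944 and of 1.95e-06 to 0.174. The count of 590 models became 189, 289 and 289 without day 0 replicates 1, 2 and 3, 176, 93 and 207 without REO replicates 1, 2 and 3, and 1430 without control day 40 replicate 2.

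**Figure D3:**
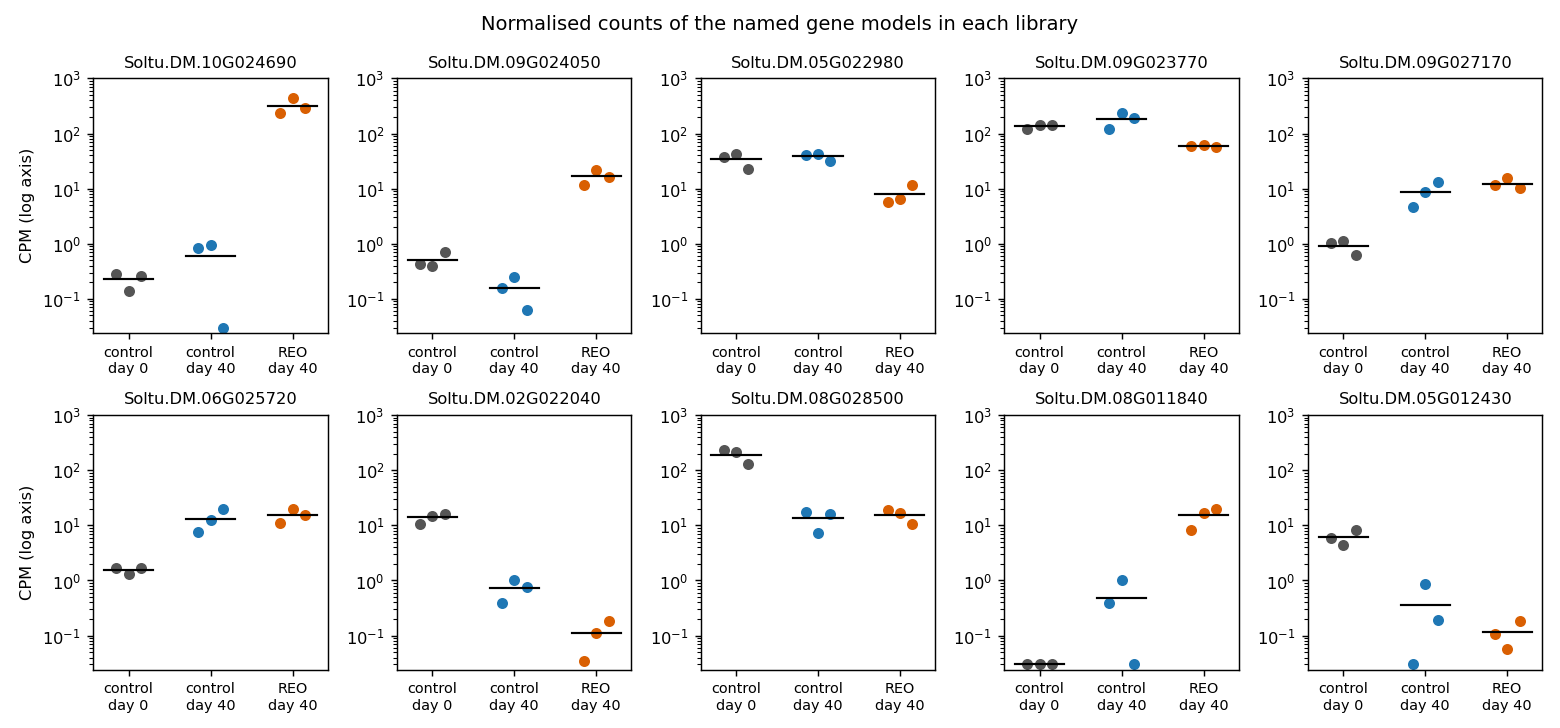
TMM-scaled CPM (log axis) of the 10 named gene models; each point is 1 library, the bar is the mean of 3 libraries and values under 0.03 CPM are drawn at 0.03. Soltu.DM.10G024690 is at 320.1 CPM on average with REO and under 1 CPM in each of the 6 control libraries.

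Whether REO moved the storage response itself was read from models called in both comparisons. Of the 96 models that rose with REO, 93 were not called in storage without REO. That comparison called 0.84% of all tested models, so most members of any list would go uncalled, and the 93 do not show separate responses. Of the 191 storage models, 3 were also called with REO at day 40: 2 fell in storage and rose with REO, and 1 rose in both. DESeq2 gave 116 in opposite directions and 26 in the same direction. In edgeR the 2 became 36 without control day 40 replicate 2, 3 without REO replicate 1, 1 without day 0 replicate 2 or control day 40 replicate 1, and 0 without any of the other 5 libraries. Lists of these sizes would share 0.547 and 0.263 models if independent, a value that leaves out the shared control day 40 libraries. In the storage comparison with REO, 118 of the 191 models were called in the same direction, 41 higher and 77 lower, against 0.86 and 1.57 for independent lists, and none (0) was called in the opposite direction. The 3 day 0 libraries serve both storage comparisons and are too few to be split between them with at least 2 each, so part of that excess may come from them. In 50 simulated data sets with no group difference at most 2 and 1 models were called in the storage comparisons without and with REO, so the at most 1 model shared there does not measure that part.

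Fold changes of all 22638 models gave the same comparison without a threshold. The correlation across genes between the storage change and the REO difference was -0.24, and simulated data with no group difference gave -0.49, because the control day 40 libraries enter both with opposite sign. The covariance was -0.161 observed and -0.163 simulated, with a simulated range of -0.181 to -0.144. Without control day 40 replicate 2, a choice made after the data were seen, the correlation was -0.46 against a simulated -0.62. The covariance was then -0.435 against a simulated -0.208, with a simulated range of -0.232 to -0.191, and 36 storage models were called in the opposite direction with REO and 4 in the same direction. Independent lists would share 4.37 and 3.16, which leaves out that the shared control libraries favour opposite directions. The covariance of the storage changes with and without REO was 0.643, against 0.164 in the simulated data. Genes were drawn independently in all these simulations. In the real data, with group means subtracted, libraries of different groups correlated across genes at -0.557 to 0.613. The simulated ranges may therefore be too narrow, and a covariance outside them does not measure an effect of REO.

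**Figure D4:**
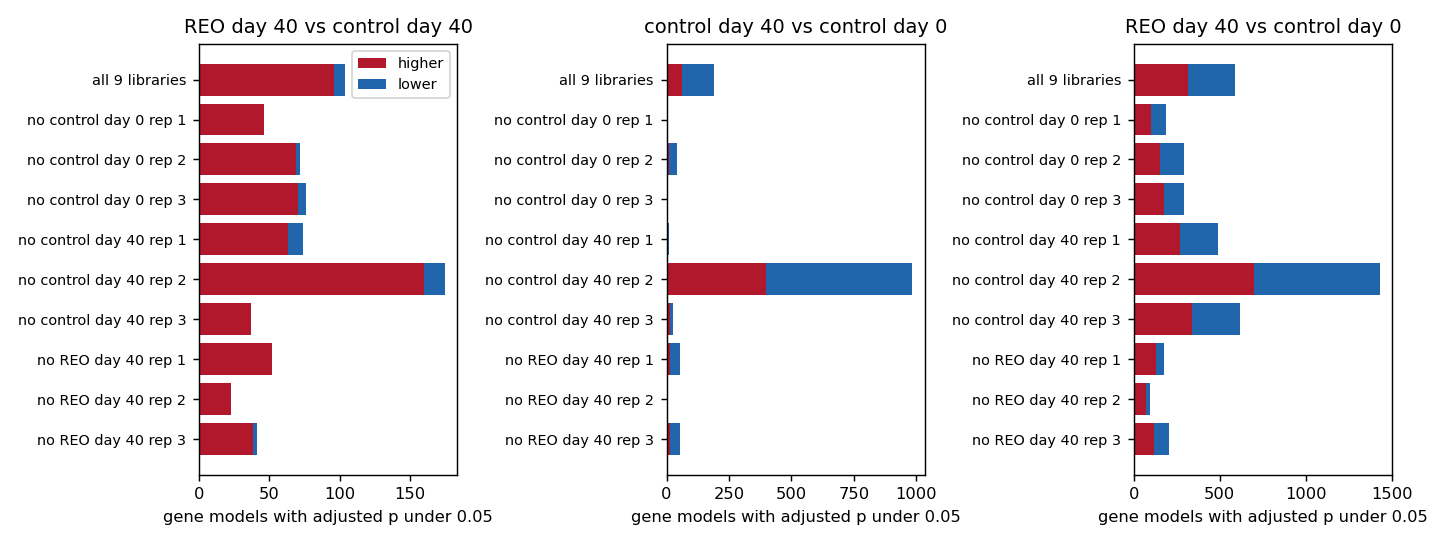
Number of gene models with an edgeR adjusted p under 0.05 in each comparison (x axis), with all 9 libraries and after leaving out each library in turn (rows); red is higher and blue is lower. Leaving out control day 40 replicate 2 raised the counts to 175, 985 and 1430.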

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

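Among the tests in this part, the check of 1 library against the excess of risen models was chosen after the result was seen. For 4 of the named gene models the storage change differed with and without REO. The difference is the REO contrast at day 40, by which these models were chosen, so it adds no evidence to that test. For Soltu.DM.10G024690 the storage change was 1.47 on the log2 scale without REO and 10.46 with it, a difference of 9.00. For Soltu.DM.09G024050 it was -1.61 and 5.04, a difference of 6.65 across 0. For Soltu.DM.05G022980 it was 0.18 and -2.10, a difference of -2.28, and for Soltu.DM.09G023770 it was 0.39 and -1.20, a difference of -1.60. The storage changes without REO of these 4 models did not pass the test.

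The excess of risen over fallen models with REO, 96 against 8, was set against 3 technical explanations. The share of risen models among calls was 0.913 or more under 3 other scalings and 0.914 without control day 40 replicate 2, which argues against both as the whole cause. The size of the excess depended on the test, since 75.2% of calls were higher with DESeq2 and 75.4% with limma-voom and library weights, the latter chosen after the data were seen. The median length scale of the risen models, from the ratio of counts to FPKM, was 1573 bases, at percentile 3.64 of 10000 expression-matched random lists. That lies inside their central 95% of 1552 to 2026 bases, close to the lower bound. A response of the tubers to REO may account for the excess, as a hypothesis found and tested on the same data, and whether libraries of a group shared a container or tuber lot is not given in the sources used here.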

How the results depend on the processing

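Added after the data were seen were library weights, leaving out control day 40 replicate 2 with REO replicate 3, and leaving out 5 abundant models. For REO against control at day 40 (104 models), DESeq2 called 516, the fit of 6 libraries 40, the replicate block 44, an adjusted p under 0.01 called 29, limma on log2(FPKM + 1) 157, library weights 682, the 2 libraries left out 69, and leaving out each library 23 to 175. For control day 40 against day 0 (191 models) the values were 1611, 0, 8, 1, 294, 2578, 916 and 0 to 985. The edgeR fit of 6 libraries with 0 calls had 2892 models at an unadjusted p under 0.05. For REO day 40 against day 0 (590 models) they were 1970, 1208, 300, 102, 699, 4126, 1010 and 93 to 1430. The 2 storage models moved back by REO became 116 with DESeq2, 1 by library size, 0 with the replicate block and 0 to 36 without single libraries. The cause of these changes was not tested, except that fewer libraries leave fewer degrees of freedom. DESeq2 made more false calls on simulated data, but those data were drawn from dispersions that edgeR estimated. They cannot rank the methods on the real data. Other scalings, filters, robust shrinkage and limma-voom moved the counts of changed genes by less than 1.5 times. Under DESeq2 all 104 REO models kept their call. The fold changes of named models kept their sign in 144 of 144 fits, and 44 of those fits lost the call. Most of these fits left out 1 library, where a sign could hardly turn, since the naming rule asked for groups that do not overlap. Replicate numbers gave no clear pairing of the libraries. Residual correlations of same-numbered libraries ran from -0.557 to 0.328, with 5 of 9 above 0.1, and those of different-numbered libraries from -0.414 to 0.613. Of the 9 libraries, 4 correlated best with their own number. Subtracting the mean of 3 libraries ties their residuals to each other, so this check cannot exclude a pairing. Alternatives for the gene lists were not run because no identifier matched a name. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Only the real split, 1 of the 10, reached the real count in each comparison: 104 against a highest other of 4, 191 against 116, and 590 against 0. The split with 116 exchanged day 0 replicate 1 with control day 40 replicate 2. At this depth and 3 libraries per group, simulation recovered 16%, 18% and 14% of 2-fold changes in the 3 comparisons, in the order above. The changed genes had a mean of at least 1 CPM, and depth was not varied alone.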

Other observations

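The tests of neighbouring models and of chromosomes were chosen after the identifiers were found without names, those on control day 40 replicate 2 after it was seen to stand apart, the swap tests after related values were seen too, and the fit without 5 models after their share was seen. Changed gene models lay beside each other, in the order of identifiers, more often than shuffled calls gave. Only tested models were ordered, 21392 of the 32819 with a chromosome number, so untested models may lie between 2 neighbours. In REO against control at day 40, 9 pairs of neighbours in this order changed in the same direction. Shuffled calls gave 0.403 on average and at most 4 in 10000 shuffles. Storage without REO had 11 such pairs against 0.92, and storage with REO had 44 against 7.78. The permutation p was 1e-04 in each (adjusted 1e-04 over 3 comparisons), the smallest these shuffles can give. With REO at day 40 the longest runs held 3 neighbours. There were 2 such runs, the first by identifier with risen models on chromosome 10. The longest in storage without REO was 4 fallen neighbours, on chromosome 3. Clusters of related genes under shared control are a candidate explanation for the 9 pairs; reads shared between near-identical or overlapping neighbours were not tested.

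By chromosome, models that rose between day 0 and day 40 with REO were fewer on chromosome 1 than its size gives, 20 against 39.2 expected (Fisher's exact test, odds ratio 0.472, adjusted p = 0.0063 over 12 chromosomes). The other chromosomes did not pass in that family, and no chromosome passed for the other comparisons or for fallen models. Fisher's test treats models as independent draws, while models called in storage with REO clustered by neighbour, so its p-value may be too small. The adjustment was made within each comparison and direction and not across them.

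Control day 40 replicate 2 stood apart from its group. Thinned to 29330673 counts, it still detected 1571 more models than the next library, which argues against depth. A swap as the whole cause is argued against by its mean correlation with the other 2 libraries of the group it would join, at most 0.925 for REO and 0.92 for day 0, where correlations within those groups were 0.956 to 0.974. Over models called with both libraries left out, REO replicates 1, 2 and 3 also lay nearer REO (1) than control (0), at 0.789, 1.06 and 0.994 with lower quartiles above the middle, while on a scale from control day 40 (0) to day 0 (1) it lay at 0.6 and day 0 replicate 1 at 0.755 with quartiles of 0.295 and 0.937, so an exchange of these beside another cause stays open. RNA of a further source in that sample is a candidate explanation: of 19313 models, among those outside the range of the other 8 libraries by at least 1 log2 unit, 456 were higher and 90 lower, a share of 0.835, against 0.768 in day 0 replicate 2 and 0.417 or less in the other 7 libraries. The same 456 models had a median of 10.5 CPM in control day 40 replicate 2, 2.71 CPM in REO replicate 3 and 1.89 CPM in day 0 replicate 2. The remaining libraries had 1.03 to 1.34 CPM, so the rise was graded and not confined to that sample. The share of 0.835 does not tell added RNA from another expression state of the same tubers. No source was identified without gene names, and a wrong label from outside the 2 groups stays open too.

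The 5 most abundant submitter-added models, with adjacent numbers, took 2.17% to 10.9% of the counts of a library, with the highest share in REO replicate 1. The mean share was 3.55% ± 1.74 (SD, n = 3) at day 0, 4.47% ± 1.60 in control tubers at day 40 and 6.63% ± 3.79 with REO. With these models left out, 114 models were called with REO, against 104 with them.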
